A study of Danio rerio with 23 samples.

How the data were processed

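The series holds RNA-seq of whole zebrafish embryos from crosses of hs:dkk1b/+ or hs:wnt8a/+ carriers, in which a heat-shock promoter drives dkk1b, a secreted Wnt antagonist, or wnt8a, a Wnt ligand, to wild-type fish. Per the labels, transgenic embryos were picked by fluorescence, their genotypically wild-type siblings were heat shocked with them, and RNA was extracted from homogenised embryos before libraries were made by standard Illumina protocols. The heat shock was 60 minutes at 37 °C for the hs:dkk1b crosses and 30 minutes at 39 °C for the hs:wnt8a crosses, each followed by recovery at 29 °C. The sample titles give 5.5 and 7.5 hours post fertilisation (hpf) and the time point field gives 5 and 7 hpf. The labels do not settle which of these is the time of heat shock and which that of collection, and the title values are used as names here. There were 8 groups and 23 libraries, 3 per group except the transgenic hs:wnt8a embryos at 5.5 hpf, with 2. Embryos came from several mating pairs, but the labels do not say that the libraries of a group came from separate clutches. The p-values of single genes therefore measure the spread between these libraries, which may be technical in part.

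The authors deposited 1 table per library with 31743 genes, and its whole-number expression values were used as read counts. The deposited TPM and RPKM columns are the authors' own length-scaled values and were not used in the tests. Per the submitters' processing notes, edgeR and the GRCz11 genome build were used, without a version for edgeR. The aligner and the counting tool are not given in the sources used here, nor is strand use in counting, so genes that overlap and near-identical copies cannot be told apart with certainty. The files give gene symbols and Ensembl identifiers, and 28988 of the identifiers were in the gene name table used here. A symbol held by more than 1 identifier was numbered (3944 names, such as wnt8a_1 and wnt8a_2). The annotation table at hand describes another assembly than GRCz11, so no coordinates are given.

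Total counts per library ran from 13845788 to 20467185 (median 16829144), with 22615 to 24244 genes having at least 1 count. The 10 most abundant genes took 7.77% to 11.4% of the counts, and mitochondrial genes 0.992% to 2.17%. Counts of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom 3.08 to 54.0 over 22 pairs), so none was treated as a copy of another. The lowest values were in siblings of hs:wnt8a, 3.08 for replicates 1 and 3 at 5.5 hpf and 3.53 for replicates 2 and 3 at 7.5 hpf. With the third library of the group these values were 32.5 and 33.6 at 5.5 hpf and 49.3 and 47.6 at 7.5 hpf. Such values cannot show whether libraries shared a clutch or pool, so 3 libraries may hold fewer independent samples.

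All 8 groups were fitted together with edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr (19504 genes tested) and the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method with 0.05 as the threshold. Each transgenic group was compared with its siblings, the effect at 7.5 hpf was compared with that at 5.5 hpf by an interaction contrast, siblings were compared between times within a line and between lines within a time, and genes changed by both transgenes were counted at each time. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F. CPM values are counts scaled to library size with TMM factors (edgeR's cpm function). A set of 23 gene lists (446 symbols, of which 7 had no match) was tested with camera in limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way. Counts "adjusted over the list alone" apply the Benjamini-Hochberg method within a list. Lists needed at least 5 tested members, and each transgene's own gene was left out of them. For 1 of the lists the results are not reported here. Some genes are in several lists, tbxta and cdx4 among them. Values were summarised with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.

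The design, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names dkk1b and wnt8a throughout. In each transgene comparison it names the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap and whose mean log2 CPM is at least 1, leaving out clone names. It adds up to 4 members with the smallest adjusted p from each list past its threshold or holding a changed gene, the strongest genes of each interaction and overlap, and a fixed set of patterning genes. The same rule was applied to the blocked fits with the condition that every pair moved the same way, which was added after seeing the data. Other genes are said in the text to be chosen after their values were seen.

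Replicate numbers are shared between groups, and the labels do not say what a number marks. Deviations from the group means were correlated between transgenic and sibling libraries of the same number. The correlations were 0.476, 0.707 and 0.551 for hs:dkk1b at 5.5 hpf, 0.606, 0.525 and 0.465 at 7.5 hpf, and 0.726, 0.307 and 0.509 for hs:wnt8a at 7.5 hpf. All were above 0.1 with 3 pairs, so in these comparisons the number was taken to pair the libraries, and fits with the replicate number as a block are given where they change a result. For hs:wnt8a at 7.5 hpf, transgenic replicate 2 with sibling replicate 3 (0.351) and transgenic replicate 3 with sibling replicate 2 (0.511) correlated as strongly as the same numbers, so only replicate 1 stood apart there and the blocked calls are less certain. The block left 7 residual degrees of freedom against 15 without it. In siblings of hs:dkk1b between the times the correlations were 0.167, 0.214 and 0.311.

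The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a fit of only the groups compared, the replicate block, a test against 1.5-fold (glmTreat) and leaving out each library. The fit was tested on simulated counts with 200 changed genes, all with a mean above 2 CPM, and a further list lowered by 1.5-fold. Of 4-fold changes it recovered 95.5% for hs:dkk1b at 5.5 hpf, 92.4% for hs:dkk1b at 7.5 hpf, 95.5% for hs:wnt8a at 5.5 hpf and 100% for hs:wnt8a at 7.5 hpf. Of 2-fold changes it recovered 59.7%, 61.2%, 38.8% and 52.2% in the same order, on 18897 to 18924 genes, and 1.04% to 5.22% of its calls were of unchanged genes. Simulated genes of like level had the same spread. The fit called 96 to 116 genes there, more than in any real transgene comparison without the block. With more changed genes the adjusted threshold is easier to pass, so recovery in the real data may be lower.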

Results

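RNA was profiled from zebrafish embryos that carried a heat-shock-driven Wnt antagonist (hs:dkk1b) or Wnt ligand (hs:wnt8a) and from their heat-shocked siblings, labelled wild-type, at 5.5 and 7.5 hpf, times around gastrulation. Each group held 3 libraries, except transgenic hs:wnt8a at 5.5 hpf with 2. Total counts per library lay between 13845788 and 20467185. The series title names Wnt control of neural plate patterning over time, and the comparisons below take each transgene against its siblings, each effect between times, and the siblings among themselves.

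The genes carried by the transgenes were examined first. In siblings of hs:dkk1b, dkk1b (ENSDARG00000045219) stood at 30.8 ± 21.1 CPM (SD, n = 3) at 5.5 hpf and 38.8 ± 18.4 CPM (SD, n = 3) at 7.5 hpf. Transgenic embryos held 3039 ± 843 CPM (SD, n = 3) and 8297 ± 9341 CPM (SD, n = 3), log2 fold changes of 6.62 ± 0.73 (SE, adjusted p = 3.60e-04) and 7.74 ± 0.76 (SE, adjusted p = 3.08e-05) by edgeR. The large spread at 7.5 hpf came from replicate 1, with 19060 CPM against 2329 and 3500. The same replicate pair stood apart in heat-shock genes, with hsp70l at 1228 CPM in the siblings and 2654 CPM in the transgenic embryos against 40.7 to 78.0 CPM in the other 4 libraries. The symbol wnt8a belonged to 2 identifiers, so reads shared between them make their levels uncertain. In the hs:wnt8a cross, wnt8a_1 (ENSDARG00000052910) stood at 3056 ± 554 CPM (SD, n = 2) in transgenic embryos at 5.5 hpf and 3652 ± 563 CPM (SD, n = 3) at 7.5 hpf. Their siblings held 567 ± 166 CPM (SD, n = 3) and 65.6 ± 99.0 CPM (SD, n = 3), and siblings of hs:dkk1b 6.08 ± 1.36 CPM (SD, n = 3) and 4.96 ± 1.17 CPM (SD, n = 3). Among siblings of hs:wnt8a at 7.5 hpf, replicate 1 held 179.7 CPM against 2.33 and 14.8 CPM. The log2 fold change of wnt8a_1 was 2.43 ± 0.84 (SE, adjusted p = 1) at 5.5 hpf, which did not pass the test, and 5.80 ± 0.93 (SE, adjusted p = 0.00730) at 7.5 hpf. The second copy, wnt8a_2 (ENSDARG00000078507), did not pass it at either time, with log2 fold changes of 0.05 ± 0.29 and -0.61 ± 0.26 (SE). Neither wnt8a gene passed the test in hs:dkk1b embryos. In hs:wnt8a embryos dkk1b was at 72.0 ± 14.7 CPM (SD, n = 3) against 21.1 ± 4.87 CPM (SD, n = 3) in siblings at 7.5 hpf, with a log2 fold change of 1.77 ± 0.59 (SE, adjusted p = 1), and at 5.5 hpf 1.07 ± 0.63 (SE, adjusted p = 1).

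**Figure D1:**
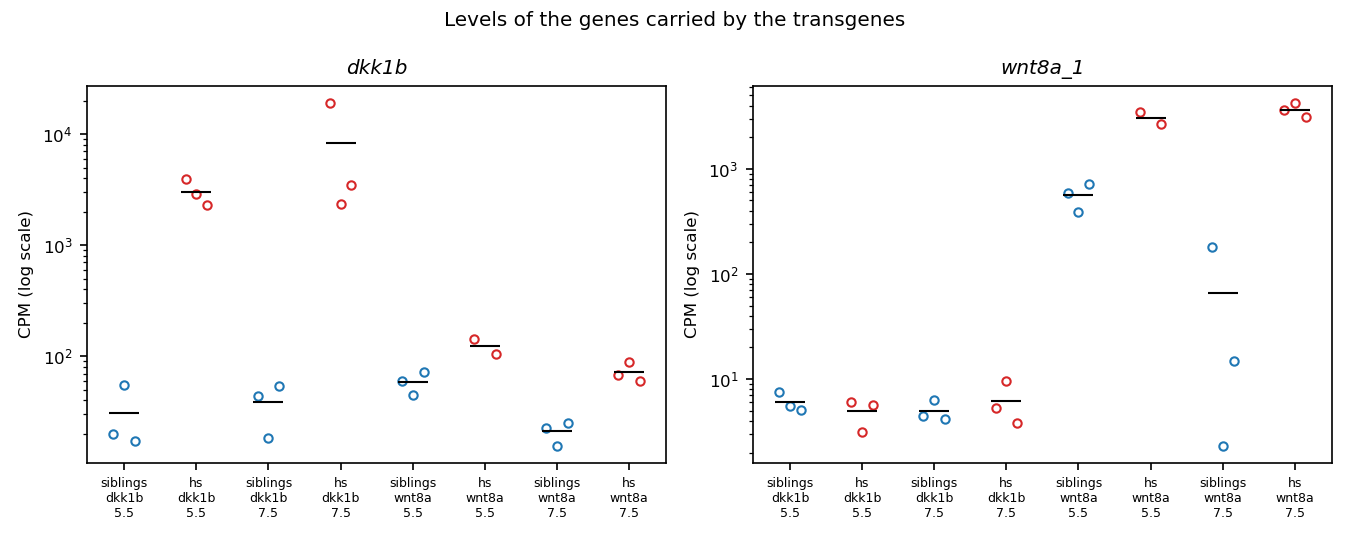
Level of dkk1b (left) and wnt8a_1 (right) in CPM on a log scale, 1 circle per library (blue siblings, red transgenic) with a bar at the group mean; line and hpf are below each group. The siblings of hs:wnt8a at 5.5 hpf lie between 391.7 and 721.5 CPM of wnt8a_1, far above the siblings of hs:dkk1b.

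At 5.5 hpf, hs:dkk1b embryos had lower levels of Wnt target and feedback genes than their siblings. The transcription factor sp5a (ENSDARG00000076571), a direct Wnt target, fell from 102 ± 23.8 CPM (SD, n = 3) to 22.0 ± 11.1 CPM (SD, n = 3), and nkd1 (ENSDARG00000020053), an intracellular Wnt inhibitor induced by the pathway, from 45.9 ± 3.92 CPM (SD, n = 3) to 16.5 ± 4.33 CPM (SD, n = 3). Of 19504 genes tested, 10 changed: dkk1b rose and 9 genes fell. The 8 largest falls were msx1b at -2.29 ± 0.28 (SE, adjusted p = 0.00110), sp5a at -2.21 ± 0.36 (SE, adjusted p = 0.0148), znf703 at -2.13 ± 0.29, the neural plate gene gbx1 at -2.01 ± 0.34 (SE, adjusted p = 0.0248), sp8b at -1.79 ± 0.31, blf at -1.66 ± 0.22, znf503 at -1.54 ± 0.25 and nkd1 at -1.48 ± 0.19 (SE, adjusted p = 0.00181) in log2 fold change. The ninth, tpbga, is named because the count holds few genes, having been chosen after its values were seen. In the fit with the replicate number as a block (the blocked fit) 48 genes changed, 3 higher and 45 lower, including all 10. They included axin2, a negative feedback regulator of the pathway, at -1.48 ± 0.23 (SE, adjusted p = 0.00853), the posterior gene hoxb1b at -2.24 ± 0.33 (SE, adjusted p = 0.00644), cdx4 at -0.89 ± 0.10 (SE, adjusted p = 5.33e-04) and tbxta, the zebrafish brachyury gene, at -0.85 ± 0.12 (SE, adjusted p = 0.00385), none of which passed without the block (adjusted p = 0.0561, 1, 0.279 and 1). Under the block krt96 was higher at 1.42 ± 0.25 (SE, adjusted p = 0.0287) and meis2b lower at -1.72 ± 0.18 (SE, adjusted p = 4.15e-04). By edgeR no gene passed when only these 6 libraries were fitted (167 at an unadjusted p under 0.05, and 27 by DESeq2 in the fit of all groups). Leaving out transgenic replicate 1 or 3 or sibling replicate 1 gave 5 genes, sibling replicate 3 gave 6, and sibling replicate 2 gave 25.

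By list, Wnt feedback genes and targets fell (median log2 fold change -0.52 over 21 genes, camera adjusted p = 7.37e-44). In this list 3 members fell and none rose over all genes, 10 fell adjusted over the list alone, the changed ones being nkd1, sp5a and sp8b. Paraxial and tailbud mesoderm genes fell (median -0.38, 26 genes, adjusted p = 1.46e-19), with no member past the test over all genes and 4 adjusted over the list alone. Its leading members were tbx16l at -0.95 ± 0.18 (adjusted p = 4.15e-04 with the block), msgn1 at -0.69 ± 0.15 (adjusted p = 0.00703 with the block) and dld at -0.57 ± 0.15 (adjusted p = 0.0159 with the block). Midbrain and midbrain-hindbrain boundary genes also fell (median -0.26, adjusted p = 3.21e-06), although their mean log2 fold change was 0.06 and sp5a was their 1 changed member, with 2 adjusted over the list alone. These 3 calls held with an estimated correlation (adjusted p = 4.41e-07, 1.07e-04 and 0.0232). With fry the Wnt feedback and paraxial calls held (adjusted p = 5.69e-05 and 0.00413) and the midbrain call was lost (adjusted p = 0.225). Hindbrain genes (median -0.08, adjusted p = 0.00124), cdx and posterior hox genes (median -0.92, adjusted p = 2.09e-09) and planar polarity genes (median -0.04, adjusted p = 0.0107) passed camera in the lower direction but not with an estimated correlation (adjusted p = 0.429, 0.0883 and 0.429). With the block and an estimated correlation the cdx and hox list passed (adjusted p = 0.0389). Adjusted over the list alone, 2, 1 and 2 members of these lists fell. The 1 changed hindbrain member was gbx1, and gbx2 and hoxb1a stood at 0.16 ± 0.79 and 0.02 ± 0.65, and wnt5b of the planar polarity list at -0.57 ± 0.13 (SE, adjusted p = 0.179). The BMP and ventral list did not pass (adjusted p = 0.399), though its member msx1b fell, with msx1a at -1.75 ± 0.33 (SE, adjusted p = 0.0561, or 0.00395 with the block). The other 16 lists, the anterior neural plate (median 0.19, adjusted p = 0.732) among them, did not pass, with adjusted p from 0.0683 to 0.938. The Wnt ligand and BMP lists had a mean of another sign than their median. Leaving out transgenic replicate 2, or sibling replicate 2 or 3, gave 11, 13 and 10 lists in place of 6.

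At 7.5 hpf, hs:dkk1b embryos had lower levels of Wnt targets and of midbrain and axial mesoderm genes. The level of axin2 (ENSDARG00000100149) was 144 ± 21.5 CPM (SD, n = 3) in siblings and 26.8 ± 4.05 CPM (SD, n = 3) in transgenic embryos, a log2 fold change of -2.42 ± 0.29 (SE, adjusted p = 2.31e-04). The notochord gene noto (ENSDARG00000021201) fell from 38.6 ± 1.48 CPM (SD, n = 3) to 13.0 ± 2.29 CPM (SD, n = 3), and tbxta from 177 ± 38.0 CPM (SD, n = 3) to 58.1 ± 10.8 CPM (SD, n = 3). In all, 30 genes changed: dkk1b rose and 29 fell. The largest falls under the rule were sp5a at -2.98 ± 0.37 (SE, adjusted p = 3.50e-04), wnt8b, a Wnt ligand of the neural tube, at -2.95 ± 0.55 (SE, adjusted p = 0.0287), blf at -2.53 ± 0.23, axin2, notum1b at -2.23 ± 0.37, msx1b at -2.13 ± 0.28, notum1a, which encodes a secreted Wnt deacylase, at -1.98 ± 0.31 and nkd1 at -1.91 ± 0.20. Of the 9 genes lower at 5.5 hpf, 8 were also lower at 7.5 hpf, against 0.0134 for independent lists (exact hypergeometric test, one-sided, p = 7.44e-23). That test treats genes as independent draws and does not measure the spread between libraries. In the blocked fit 146 genes changed, 31 higher and 115 lower, including all 30. Among the higher were fezf2 of the anterior neural plate list at 0.73 ± 0.13 (SE, adjusted p = 0.0139), rx3, an eye field gene of the same list, at 0.52 ± 0.10 (SE, adjusted p = 0.0172), the pan-neural gene sox2 at 0.68 ± 0.09 (SE, adjusted p = 0.00153), and nkx2.7 of the endoderm list at 1.25 ± 0.20 (SE, adjusted p = 0.00496). Without the block these stood at 0.73 ± 0.70 (SE, adjusted p = 1), 0.55 ± 0.50, 0.67 ± 0.17 and 1.24 ± 0.31, none past the test. Also past the test under the block alone were cdx4 at -1.07 ± 0.10 (SE, adjusted p = 4.50e-05), hoxb1b at -1.20 ± 0.24 (SE, adjusted p = 0.0279), gbx1 at -1.48 ± 0.17 (SE, adjusted p = 4.83e-04), sp5l at -1.05 ± 0.11 (SE, adjusted p = 1.73e-04) and fgf8a at -0.49 ± 0.08 (SE, adjusted p = 0.00967). Leaving out transgenic replicate 1, 2 or 3 gave 15, 15 and 16 genes, and sibling replicate 1 gave 16. Leaving out both libraries of replicate 1, which had the high heat-shock gene levels, gave 10 genes, a choice made after seeing the data. Without both libraries of replicate 2 or of replicate 3 the counts were 12 and 12, so the drop was not particular to replicate 1.

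Wnt feedback genes and targets fell at 7.5 hpf (median -0.78, 21 genes, camera adjusted p = 1.38e-58), with 8 members lower over all genes and 11 adjusted over the list alone. They included lef1, a transcription factor of the pathway, at -1.22 ± 0.15 (SE, adjusted p = 3.15e-04). Midbrain and boundary genes fell (median -0.49, adjusted p = 3.09e-23), 4 over all genes and 6 adjusted over the list alone. Among them en2a, a midbrain-hindbrain transcription factor, was at -4.31 ± 0.77 (SE, adjusted p = 0.0184), resting on 5 counts over the transgenic group, irx7 at -0.89 ± 0.16 (SE, adjusted p = 0.0204) and her5 at -1.30 ± 0.26 (SE, adjusted p = 0.0451), while pax2a was at -0.62 ± 0.62. Paraxial and tailbud genes fell (median -0.22, adjusted p = 8.29e-09), with 2 members lower over all genes, tbx16l at -1.14 ± 0.19 (SE, adjusted p = 0.00785) and tbxta at -1.61 ± 0.32 (SE, adjusted p = 0.0428), and 8 adjusted over the list alone. Dorsal organizer and axial mesoderm genes fell too (median -0.13, adjusted p = 1.07e-05). Their 2 changed members were noto at -1.56 ± 0.19 (SE, adjusted p = 3.50e-04) and tbxta, also 2 adjusted over the list alone, whereas gsc and chrd stood at 0.23 ± 0.26 and -0.39 ± 0.28. These 4 calls held with an estimated correlation (adjusted p = 4.15e-08, 3.70e-05, 0.00358 and 8.59e-04). Hindbrain (median -0.22, adjusted p = 5.07e-05), cdx and posterior hox (median -0.28, adjusted p = 1.89e-04) and FGF pathway genes (adjusted p = 0.00411) passed camera in the lower direction and not with an estimated correlation (adjusted p = 0.231, 0.319 and 0.0683). The changed hindbrain member was irx7. Adjusted over the list alone 3, 2 and 3 of their members fell. The FGF list had a median of 0.01 and a mean of -0.36, its changed member being fgf24 at -1.49 ± 0.25 (SE, adjusted p = 0.0101). The anterior neural plate list passed camera in the higher direction (median 0.42, 18 genes, adjusted p = 0.00411) but not with an estimated correlation (adjusted p = 0.359). With the block it passed both ways (adjusted p = 8.98e-07, and 0.0110 with an estimated correlation), with 2 members higher over all genes and 8 adjusted over the list alone, against 2 without the block. Without the block otx2a, hesx1, otx2b and six3b stood at 0.58 ± 0.17, 0.45 ± 0.14, 0.48 ± 0.49 and 0.31 ± 0.24. The Wnt ligand and receptor list did not pass (adjusted p = 0.317), though its member fzd9b fell, at -1.16 ± 0.18 (SE, adjusted p = 0.00573), nor did the BMP list (adjusted p = 0.583). The other 13 lists had adjusted p from 0.0943 to 0.991. Mean and median differed in sign for the Wnt ligand, BMP, planar polarity, chaperone, pan-neural and endoderm lists, and for retinoic acid genes the test pointed lower with both above 0. Of these other lists, the yolk syncytial layer list passed in the lower direction with the block (adjusted p = 0.0268, and 0.446 with an estimated correlation).

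**Figure D2:**
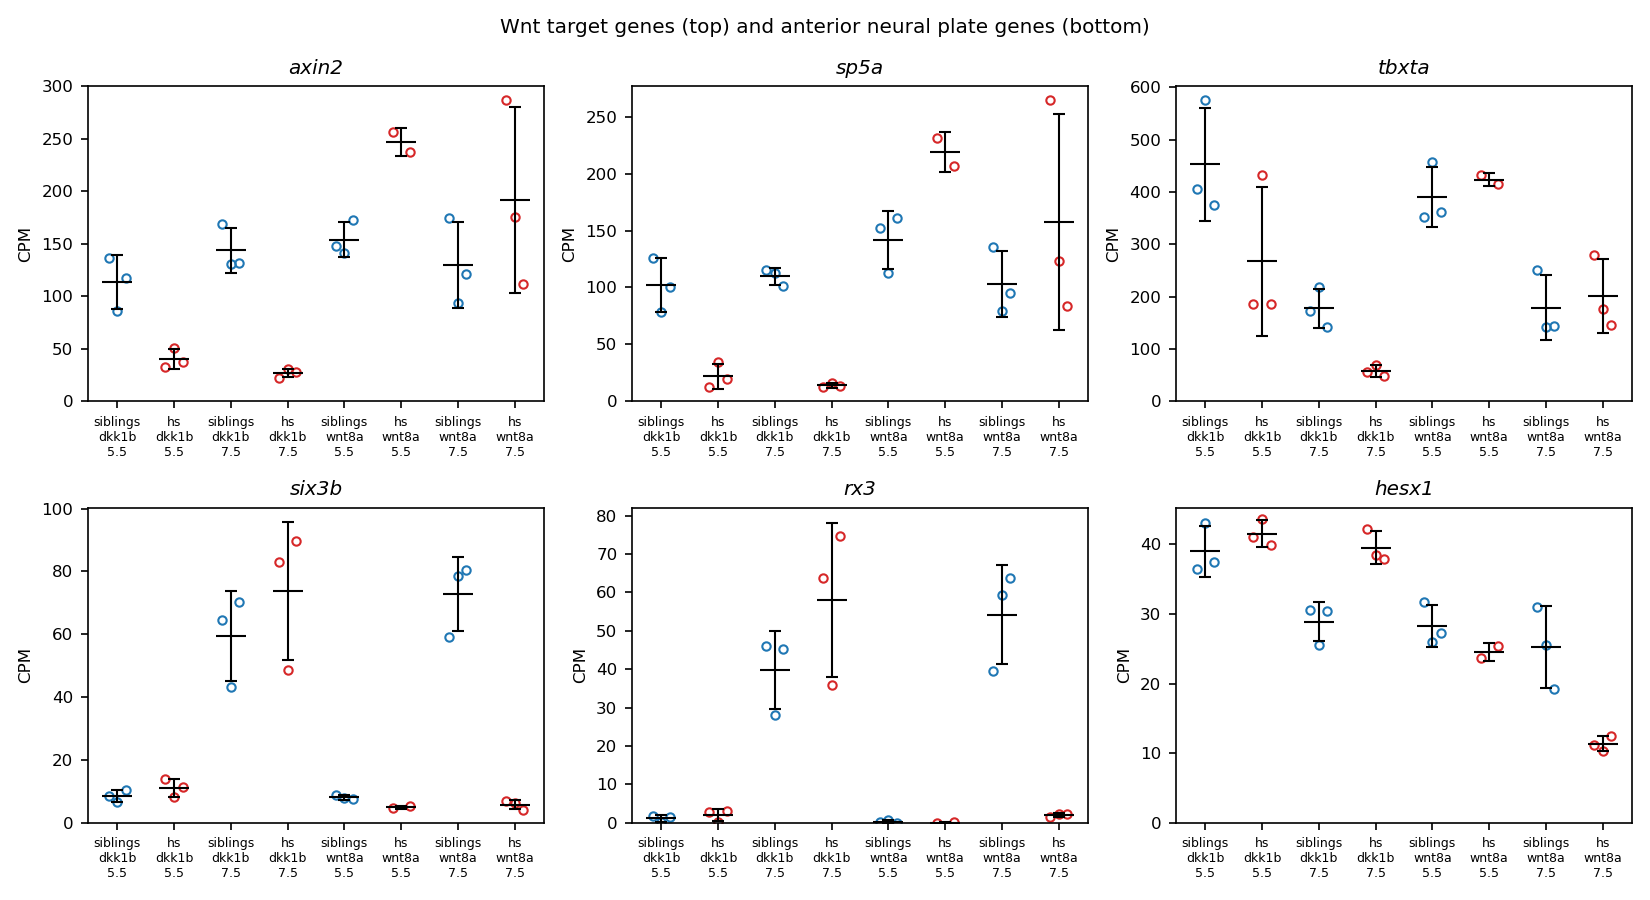
Level in CPM of axin2, sp5a and tbxta (top) and six3b, rx3 and hesx1 (bottom), 1 circle per library (blue siblings, red transgenic), with mean and SD in black; line and hpf are below each group. At 7.5 hpf the top genes are lower in hs:dkk1b embryos and the bottom genes lower in hs:wnt8a embryos, where six3b has a mean of 5.75 against 72.8 CPM.

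Whether the hs:dkk1b effect differed between the times was tested by the interaction. No gene passed by edgeR (170 genes at an unadjusted p under 0.05, and 1 gene by DESeq2). In the blocked fit 3 genes passed, all with a stronger fall at 7.5 hpf: notum1a with a difference in log2 fold change of -1.86 ± 0.21 (SE, adjusted p = 0.00702), noto with -1.59 ± 0.21 (SE, adjusted p = 0.0131) and ism1, which encodes a secreted protein, with -1.04 ± 0.13 (SE, adjusted p = 0.00903). The level of noto at 5.5 hpf was 46.5 ± 9.39 CPM (SD, n = 3) in siblings and 47.5 ± 12.8 CPM (SD, n = 3) in transgenic embryos. For sp5a and axin2 the differences were -0.77 ± 0.49 (SE, adjusted p = 1) and -0.94 ± 0.39 (SE, adjusted p = 1), and for gbx1 and hoxb1b 0.54 ± 0.47 and 1.18 ± 0.86 (SE), none past the test.

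At 5.5 hpf no gene differed between hs:wnt8a embryos (n = 2) and their siblings (n = 3) by edgeR, with 649 genes at an unadjusted p under 0.05 and 5 genes, all lower, by DESeq2. Wnt targets had higher means without passing the test: axin2 was at 247 ± 13.4 CPM (SD, n = 2) against 154 ± 16.4 CPM (SD, n = 3), a log2 fold change of 0.68 ± 0.30 (SE, adjusted p = 1), and sp5a at 0.63 ± 0.38 (SE). Anterior neural plate genes were the list with the smallest adjusted p, lower by camera (median -0.75, 18 genes, adjusted p = 5.36e-07) but not with an estimated correlation (adjusted p = 0.363). None of its members passed over all genes and 3 did adjusted over the list alone. The forebrain and midbrain genes otx1, otx2a and otx2b stood at -1.33 ± 0.35, -0.76 ± 0.20 and -2.18 ± 0.72 (SE), otx2b at -1.33 without sibling replicate 2, which held 17.0 CPM against 5.98 and 4.0. The list passed camera without that library too (median -0.70, adjusted p = 2.95e-05). Of its other members, six3a and six3b stood at -1.0 ± 0.43 and -0.72 ± 0.31, and rx3 was at most 0.671 CPM in any of these libraries. Heat-shock chaperone genes (median 0.26, adjusted p = 0.0289) and maternal genes (median 0.32, adjusted p = 0.01) passed camera in the higher direction, neither with an estimated correlation (adjusted p = 0.560 and 0.560) and neither with a member past the test over all genes or adjusted over the list alone. Examples were hsp70l at 0.26 ± 1.25 and btg4 at 0.50 ± 0.60 (SE). Of the others, 19 lists had adjusted p from 0.0714 to 0.978, with Wnt feedback genes at a median of 0.12 (adjusted p = 0.0714). Signs of mean, median and test were not the same for the midbrain, hindbrain, neural plate border and paraxial lists. Leaving out sibling replicate 1 gave 2 lists in place of 4. The siblings in this comparison held wnt8a_1 at 18.6% of the transgenic mean.

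At 7.5 hpf, hs:wnt8a embryos had far lower levels of forebrain and eye field genes than their siblings. The eye field gene rx3 (ENSDARG00000052893) was at 54.2 ± 13.0 CPM (SD, n = 3) in siblings and 2.03 ± 0.507 CPM (SD, n = 3) in transgenic embryos, six3b (ENSDARG00000054879), a forebrain transcription factor, at 72.8 ± 11.8 CPM (SD, n = 3) and 5.75 ± 1.48 CPM (SD, n = 3), and fezf2 at 49.6 ± 12.5 CPM (SD, n = 3) and 0.489 ± 0.268 CPM (SD, n = 3). In all 19 genes changed: wnt8a_1 rose and 18 fell. The 8 largest falls were lhx2b at -7.14 ± 1.06 (SE, adjusted p = 0.00370), resting on 4 counts over the transgenic group against 692 over the siblings, fezf2 at -6.60 ± 1.0 (SE, adjusted p = 0.00448), six7 at -5.47 ± 0.57, rx3 at -4.72 ± 0.61 (SE, adjusted p = 7.28e-04), six3b at -3.66 ± 0.28 (SE, adjusted p = 5.85e-07), pax6b, an eye and forebrain gene, at -3.02 ± 0.50, nkx2.7 at -3.01 ± 0.42 and arr3b at -2.84 ± 0.47. In the blocked fit 75 genes changed, 20 higher and 55 lower, including all 19. Among the higher were the Wnt ligand gene wnt8b at 1.08 ± 0.21 (SE, adjusted p = 0.0401), the neural plate border gene pax3a at 1.06 ± 0.13 (SE, adjusted p = 8.82e-04), her5, a midbrain-hindbrain boundary gene, at 0.96 ± 0.16 (SE, adjusted p = 0.0148), her11 at 0.89 ± 0.13 (SE, adjusted p = 0.004), nkd1 at 0.79 ± 0.14 (SE, adjusted p = 0.0246) and lef1 at 0.47 ± 0.08 (SE, adjusted p = 0.0219). Without the block nkd1 stood at 0.80 ± 0.19 (SE, adjusted p = 0.263, or 0.0246 with the block). At 0.56 ± 0.27 and 0.61 ± 0.34 (SE) without the block, axin2 and sp5a passed in neither fit. Both were higher in transgenic replicates 1 and 2 than in siblings of the same number, but lower in replicate 3. There axin2 was at 111.6 CPM in transgenic embryos against 121.5 CPM in siblings, and sp5a at 84.09 against 95.04 CPM. Leaving out transgenic replicate 2 gave 11 genes, and a fit of these 6 libraries alone gave 9, all lower, 6 of them among the 19.

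Anterior neural plate genes fell as a list (median -1.53, 18 genes, camera adjusted p = 3.87e-107, and 4.24e-07 with an estimated correlation). Of them 9 fell over all genes, 11 adjusted over the list alone, and none rose. In the list six7 stood at -5.47 ± 0.57 (SE, adjusted p = 4.89e-05) and hesx1, a forebrain repressor, at -1.16 ± 0.15 (SE, adjusted p = 7.28e-04), and otx2b was at -0.92 ± 0.49 (SE, adjusted p = 1, or 0.0233 with the block). Wnt feedback genes and targets were higher as a list (median 0.29, adjusted p = 2.86e-07, and 0.00704 with an estimated correlation), with no member past the test over all genes and 2 adjusted over the list alone. This call was lost with fry (adjusted p = 0.0791), and with the block and an estimated correlation (adjusted p = 0.140). Pan-neural genes were lower (median -0.05, mean -0.36, adjusted p = 2.30e-04, and 0.0338 with an estimated correlation, 0.0602 with the block as well). They did not pass with fry (adjusted p = 0.151). Their 1 changed member was sox2 at -1.36 ± 0.17 (SE, adjusted p = 7.28e-04), and 4 were lower adjusted over the list alone. The other calls by camera were Wnt ligands and receptors (median -0.01, adjusted p = 0.0110), hindbrain (median -0.01, adjusted p = 0.0157), endoderm and Nodal (median -0.09, adjusted p = 0.0110) and neural plate border genes (median -0.11, adjusted p = 0.0265) in the lower direction. Midbrain and boundary (median 0.09, adjusted p = 0.00541), yolk syncytial layer (median 0.12, adjusted p = 0.0110) and heat-shock chaperone genes (median 0.14, adjusted p = 0.0110) passed in the higher direction. With an estimated correlation none of these 7 passed (adjusted p from 0.190 to 0.430). Adjusted over the list alone, 2 Wnt ligand and receptor genes were higher and 2 lower, 3 midbrain genes were higher, 1 hindbrain, 2 endoderm and 1 neural plate border gene were lower, and no yolk or chaperone gene passed. Over all genes the changed members were fzd8a, a Wnt receptor gene, at -1.76 ± 0.14 (SE, adjusted p = 1.23e-06) and nkx2.7 of the endoderm list, while cyp26c1 of the hindbrain list was at -2.95 ± 0.63 (SE, adjusted p = 0.135, or 5.05e-05 with the block) and zic1 of the border list at -1.82 ± 0.43 (SE, adjusted p = 0.296, or 5.05e-05 with the block). The dorsal organizer list did not pass (adjusted p = 0.696), though its member gsc, a prechordal plate gene, fell, at -1.92 ± 0.28 (SE, adjusted p = 0.00279). The remaining 12 lists had adjusted p from 0.0550 to 0.668. The dorsal organizer and retinoic acid lists had a median above 0 and a mean below 0. Leaving out transgenic replicate 2 gave 6 lists in place of 10. Without the block 4 lists of other tissues or dividing cells passed in none of the transgene comparisons: the adjusted p by camera, for hs:dkk1b at 5.5 and 7.5 hpf and hs:wnt8a at 5.5 and 7.5 hpf, was 0.938, 0.249, 0.978, 0.260 for the outer enveloping layer list, and 0.537, 0.562, 0.945, 0.273 for the blood and vascular precursors list, and 0.399, 0.517, 0.619, 0.668 for the germ cells list, and 0.765, 0.619, 0.249, 0.596 for the cell cycle list. With the block the paraxial, BMP, FGF and retinoic acid lists passed too (adjusted p = 0.0467, 0.0123, 0.0201 and 0.00429), none of them with an estimated correlation (adjusted p = 0.552, 0.191, 0.191 and 0.191).

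**Figure D3:**
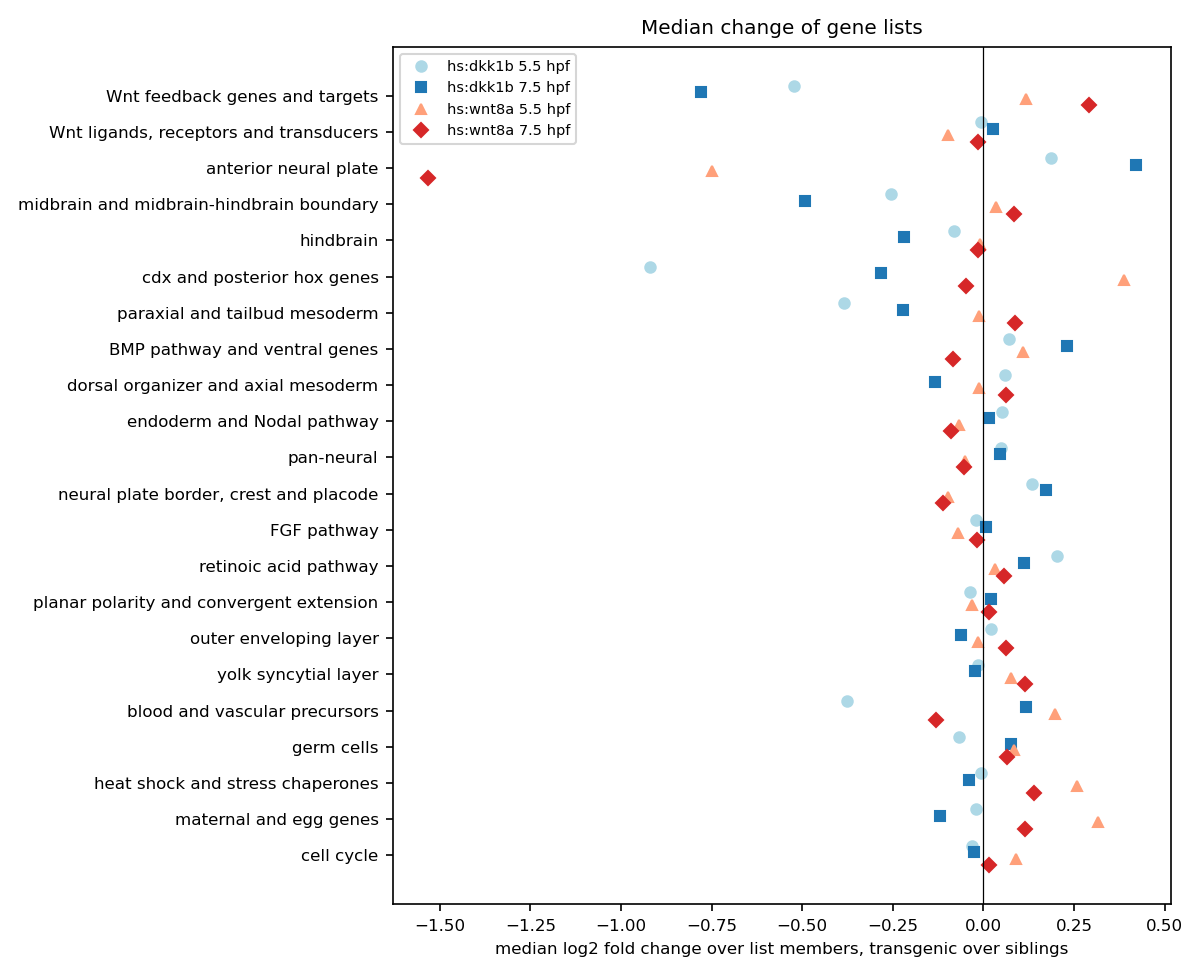
Median log2 fold change of gene lists, transgenic over siblings (x axis), with 1 marker per comparison (line and hpf in the key); no error is drawn. Anterior neural plate genes have a median of -1.53 in hs:wnt8a embryos at 7.5 hpf, and Wnt feedback genes -0.78 in hs:dkk1b embryos.

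The hs:wnt8a effect differed between the times for 1 gene by edgeR (340 at an unadjusted p under 0.05). Siblings at 5.5 hpf held wnt8a_1 at 18.6% of the transgenic mean, which may narrow the contrast at that time. The forebrain gene six3b stood at 8.06 ± 0.727 CPM (SD, n = 3) in siblings and 4.88 ± 0.505 CPM (SD, n = 2) in transgenic embryos at 5.5 hpf, and the difference between its log2 fold changes at 7.5 and 5.5 hpf was -2.94 ± 0.40 (SE, adjusted p = 0.00946). Leaving out sibling replicate 3, or transgenic replicate 1 or 2, of the 5.5 hpf groups left no gene past the threshold by edgeR, with 528, 330 and 316 at an unadjusted p under 0.05. By DESeq2, with all libraries, 4 genes passed. Leaving out sibling replicate 1 or transgenic replicate 2 of the 7.5 hpf groups gave 2. For rx3 the difference was -1.95 ± 4.21 and for hesx1 -0.95 ± 0.22 (SE, adjusted p = 0.818), and for axin2 -0.12 ± 0.40 (SE).

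Genes changed in opposite directions by both transgenes were then counted. No gene was changed by both at 5.5 or at 7.5 hpf in the edgeR fits without the block (at an unadjusted p under 0.05, 277 and 649 genes in the hs:dkk1b and hs:wnt8a comparisons at 5.5 hpf, and 520 and 309 at 7.5 hpf). Without transgenic hs:wnt8a replicate 3 at 7.5 hpf, 1 gene was. At 7.5 hpf 6 genes were changed in opposite directions by DESeq2, and 16 in the blocked fits, with none in the same direction. Of these, 10 were lower in hs:dkk1b and higher in hs:wnt8a embryos (0.118 expected of independent lists, exact hypergeometric test, one-sided, p = 5.99e-18): lef1, nkd1, tpbga, her5, wnt8b, pax3a, en2a, ism1, lmo4a and prrx1b. The other 6 were higher in hs:dkk1b and lower in hs:wnt8a embryos (0.0874 expected, p = 2.65e-10 by the same exact test): rx3, fezf2, sox2, nkx2.7, fzd8a and shisa2a. Those of the 16 beyond the 8 the rule takes were chosen after their values were seen. Some rested on few counts in a transgenic group. Over hs:dkk1b embryos prrx1b and en2a had 3 and 5 counts, against 55 and 113 in siblings. Over hs:wnt8a embryos nkx2.7 and fezf2 had 15 and 29 counts, against 135 and 3111 in siblings. The hypergeometric test treats genes as independent draws, which genes that move together are not. Its p-values therefore do not measure the spread between libraries. The 2 comparisons used separate siblings. Blocked calls in hs:wnt8a embryos at 7.5 hpf are less certain, since replicates 2 and 3 correlated across numbers as strongly as within them. All 18 genes lowered in hs:wnt8a embryos at 7.5 hpf without the block had log2 fold changes above 0 in hs:dkk1b embryos, and 28 of the 29 lowered in hs:dkk1b embryos had the opposite sign in hs:wnt8a embryos, most of these values not past the test.

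Heat-shocked siblings were compared between the times. Their list members are given as counts, as the lists were not tested here. Siblings of hs:wnt8a at 5.5 hpf held wnt8a_1 at a mean of 567 CPM, so changes in that line may not be of stage alone. Anterior and posterior patterning genes were among those that rose in both lines: six3b by 2.82 (adjusted p = 2.88e-06) in siblings of hs:dkk1b and 3.17 (adjusted p = 9.60e-07) in siblings of hs:wnt8a in log2 fold change, rx3 by 5.13 (adjusted p = 3.25e-05) and 7.58 (adjusted p = 3.88e-06), and hoxb1b by 2.24 (adjusted p = 0.00927) and 3.90 (adjusted p = 1.98e-04). Of 18 anterior neural plate genes 11 and 12 rose and 3 and 0 fell. Of 17 cdx and posterior hox genes 16 rose and 1 fell in each line, and of 22 hindbrain genes 16 and 14 rose and 1 and 2 fell. Of 24 cell cycle genes 15 and 21 fell and 2 and 0 rose, and of 20 maternal genes 10 and 14 fell and none rose. In siblings of hs:dkk1b 6050 genes changed (3046 higher, 3004 lower), and in siblings of hs:wnt8a 7840 (4259 higher, 3581 lower). Both lines called 4547 genes, 4539 in the same direction and 8 in opposite directions, against 2432 shared calls expected of independent lists. Leaving out hs:dkk1b sibling replicate 2 at 5.5 hpf gave 3628 genes.

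Between the siblings of the 2 lines, 1508 genes differed at 5.5 hpf (608 higher and 900 lower in siblings of hs:wnt8a) and 345 at 7.5 hpf (181 higher, 164 lower). The lines received different heat shocks and differed in position in the sequencing run. Line could therefore not be separated from either, nor from a difference in stage. The genes named here, other than wnt8a_1 and otx2b, were chosen after their values were seen. At 5.5 hpf the anterior neural plate list had 5 of 18 members lower in siblings of hs:wnt8a and a median of -1.13, with six3a at -1.75 (adjusted p = 0.00557), otx2b at -2.15 (adjusted p = 0.0198) and fezf2 at -3.60 (adjusted p = 0.0286). The cdx and hox list had 4 of 17 lower, hoxb9a at -3.72 (adjusted p = 0.0145) among them. Of 24 cell cycle genes 4 were higher and none lower (median 0.27), and of 20 maternal genes 1 was lower and none higher (median 0.26). Of 23 chaperone genes 3 were higher and 1 lower, with hspa5, an endoplasmic reticulum chaperone gene, at 1.99 (adjusted p = 0.0372), and nkd1 stood at 0.84 (adjusted p = 0.0112). The chaperone gene hsp70.3 was at 1054 ± 536 CPM (SD, n = 3) in siblings of hs:dkk1b and 11040 ± 3938 CPM (SD, n = 3) in siblings of hs:wnt8a, with a log2 fold change of 3.39 (adjusted p = 0.0540), not past the test. The gene wnt8a_1 differed by 6.55 (adjusted p = 0.00101) at 5.5 hpf and 3.72 (adjusted p = 0.0381) at 7.5 hpf, where the call rested on replicate 1 of hs:wnt8a (log2 fold change 0.79, adjusted p = 0.408 without it) and was also lost without any 1 of the hs:dkk1b siblings (adjusted p up to 0.125). With each library left out in turn at 5.5 hpf, wnt8a_1 and six3a kept their calls, while otx2b, fezf2, hoxb9a, hspa5 and nkd1 did not (highest adjusted p = 0.113, 0.142, 0.08, 0.120 and 0.0638). At 7.5 hpf no anterior neural plate gene differed. At 5.5 hpf leaving out hs:dkk1b sibling replicate 1 or 3 gave 537 and 478 genes, and hs:wnt8a sibling replicate 1 or 3 gave 424 and 353. At 7.5 hpf leaving out hs:dkk1b sibling replicate 1, 2 or 3 gave 160, 119 and 111 genes, and hs:wnt8a sibling replicate 2 or 3 gave 106 and 55. Fits of these groups alone gave 466 and 23 genes.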

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

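The test of the earlier-stage explanation was set before its result was seen, the interaction contrasts were planned, and the other tests of explanations and the splits were chosen only after the results were seen. Groups of 2 or 3 libraries were too small for a test of single outlying libraries.

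The hs:wnt8a effect on six3b differed between 7.5 and 5.5 hpf by -2.94 on the log2 scale in the interaction test. With the replicate block, the hs:dkk1b effect differed between the times for notum1a (-1.86), noto (-1.59) and ism1 (-1.04). The interaction of hs:dkk1b without the block gave 0 genes by edgeR (170 at an unadjusted p under 0.05, 1 by DESeq2). All 100 of its 100 splits reach a real count of 0 by construction (highest other 26), so they say nothing about chance.

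The fall of anterior neural plate genes in hs:wnt8a embryos at 7.5 hpf was weighed against 2 technical explanations. If the transgenic embryos were younger than their siblings, genes that rise with stage would be lower too. The 300 genes that rose most in siblings of the other line were taken, leaving out all listed genes. Their median log2 fold change was -0.0113 (95% bootstrap interval -0.0471 to 0.0165) against -1.53 for the list. The interval does not measure the spread between libraries. Genes that fell most in those siblings had a median of 0.059. On the stage score described under Other observations, transgenic minus sibling was 0.0333, -0.121 and 0.00368 in pairs 1, 2 and 3. A slightly earlier stage in pair 2 therefore remains possible. The list's median difference in these pairs was -1.57, -1.52 and -1.67, which argues against stage as the main source of the fall. If a stronger heat-shock response in transgenic libraries lay behind it, the fall would follow hsp70.3, but the median fall in the pair with the smallest hsp70.3 ratio (0.959) was 1.03 times that in the pair with the largest (3.14), and 17 of 18 genes were lower in every pair. An effect of the hs:wnt8a transgene, which the design names, remains as a hypothesis.

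The wnt8a_1 reads in siblings of hs:wnt8a at 5.5 hpf are the second pattern. Reads moved between the wnt8a copies cannot supply them, since the lowest sum of both copies was 5.75 times the highest in siblings of hs:dkk1b. Leakage between libraries at a common rate would give similar counts in all 12 sibling libraries, where the highest was 221.8 times the lowest. Leakage at a rate that differs between libraries was not tested and remains open for these reads. Transgenic embryos among those pooled as siblings may account for them, since the siblings held 18.6% of the transgenic mean (12.8% to 23.6% by library), but RNA of the transgene in non-transgenic embryos, such as RNA supplied by a carrier mother, would give the same values, and the labels do not say which parent carried it. These cannot be told apart here.

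The third pattern is that no gene passed the test in hs:wnt8a embryos at 5.5 hpf by edgeR (649 at an unadjusted p under 0.05, 5 by DESeq2). Too few libraries to see a change remains open, as 38.8% of simulated 2-fold changes were recovered in this comparison. Of simulated 4-fold changes 95.5% were recovered, but the simulation gave genes of like level the same spread and no wnt8a_1 to siblings. It cannot exclude that changes of that size were missed here. The gene wnt8a_1 itself, at 2664 and 3447 CPM in transgenic embryos against 391.7 to 721.5 CPM in siblings, did not pass. Since changes may be missed, a single sibling library of later stage cannot be told apart, although 0 genes passed without sibling replicate 2 by edgeR (265 at an unadjusted p under 0.05). RNA of wnt8a in the siblings may have narrowed the contrast: Wnt feedback genes had a median log2 change of 0.159 in siblings of hs:wnt8a over siblings of hs:dkk1b, with 12 of 21 above 0, but the lines also differed in heat shock, so this cannot be told apart. A weaker response of younger embryos, which the design also allows, remains open, as the interaction passed for six3b (-2.94) and for no other gene by edgeR (340 at an unadjusted p under 0.05, 4 by DESeq2). The interaction cannot separate such a response from the wnt8a_1 RNA in siblings. That RNA stood at 12.8% to 23.6% of the transgenic mean at 5.5 hpf, against 0.0639%, 0.405% and 4.92% at 7.5 hpf.

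With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For hs:dkk1b at 5.5 hpf 4 of 10 splits gave at least the real 10 genes, the highest other 515, from a split that puts both replicate 2 libraries on one side, which points to a structure of the samples (48 genes in the blocked fit). At 7.5 hpf 1 of 10 gave the real 30 (highest other 21). For hs:wnt8a at 7.5 hpf 2 of 10 gave at least 19, the highest other, 702, coming from a split with both replicate 1 libraries on one side and again pointing to a structure of the samples (75 genes in the blocked fit). Among the 4 splits that part all 3 pairs, the other 3 gave 0 genes in each of these comparisons and at most 4, 6 and 10 lists, against the real 6, 8 and 10. Siblings between times gave 6050 (hs:dkk1b) and 7840 (hs:wnt8a), 1 of 10 splits each, the highest other 0. Between lines they gave 1508 at 5.5 hpf (1 of 10, highest other 575) and 345 at 7.5 hpf (1 of 10, highest other 0). For gene lists, 5 of 10 splits gave at least the real 6 in hs:dkk1b at 5.5 hpf (highest other 13), 2 of 10 at least 8 at 7.5 hpf (highest other 10) and 2 of 10 at least 10 in hs:wnt8a at 7.5 hpf (highest other 10). For genes changed in opposite directions at 7.5 hpf without the block the real count was also 0, which 100 of 100 splits reach by construction (highest other 1), so they say nothing about chance either.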

How the results depend on the processing

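Chosen only after the results were seen were the fits without a whole replicate number and the block with an estimated correlation. DESeq2 size factors moved no count by over 1.5 times. The DESeq2 test gave 27 genes for hs:dkk1b at 5.5 hpf, 59 at 7.5 hpf, 5 and 29 for hs:wnt8a at 5.5 and 7.5 hpf, 1 and 4 for the hs:dkk1b and hs:wnt8a interactions, 6 in opposite directions at 7.5 hpf and 913 between siblings at 7.5 hpf. Without the filter the siblings at 7.5 hpf gave 205 genes and hs:wnt8a at 7.5 hpf 5 lists. Fitting only the groups compared gave 0 genes for hs:dkk1b at 5.5 hpf, 9 for hs:wnt8a at 7.5 hpf, 2 for its interaction, and 466 and 23 between siblings. A test against 1.5-fold, which asks for a larger change, gave 4 and 9 (hs:dkk1b), 12 (hs:wnt8a at 7.5 hpf), 1559 and 3021 (siblings between times) and 115 and 23 (siblings between lines). The replicate block gave 48 and 146 genes (hs:dkk1b), 75 (hs:wnt8a at 7.5 hpf), 3 (hs:dkk1b interaction) and 16 in opposite directions at 7.5 hpf. Where the numbers did not pair the libraries the block gave 113 (hs:wnt8a at 5.5 hpf, correlations -0.068 and -0.087), 19 (hs:wnt8a interaction), 4392 (hs:wnt8a siblings, -0.300, -0.256 and 0.175), 3 (siblings at 5.5 hpf) and 7 (siblings at 7.5 hpf). With an estimated correlation 3, 4, 0 and 3 lists passed (hs:dkk1b, then hs:wnt8a, by time), with fry 2, 4, 0 and 1, and with the block and an estimated correlation 5 (hs:dkk1b at 7.5 hpf), 1 and 1 (hs:wnt8a). Except for the test against 1.5-fold, the causes were not tested. Of the values of named genes under the replicate block, 217 kept their side of the threshold, 82 came in and 0 fell out, many having been named because they passed in the blocked fit. Leaving out 1 of the 2 transgenic hs:wnt8a libraries at 5.5 hpf leaves 1, which is assumed to vary like the other groups. Without replicate 1, 2 or 3 of both groups, hs:dkk1b gave 1, 23 and 4 genes at 5.5 hpf and 10, 12 and 12 at 7.5 hpf, and hs:wnt8a at 7.5 hpf 12, 9 and 5; with the replicate block 17, 49 and 18, then 53, 63 and 62, then 52, 38 and 42. Leaving out 1 library gave 5 to 25 and 15 to 23 genes (hs:dkk1b), 0 and 11 to 17 (hs:wnt8a), 0 and 0 to 2 (interactions), 3628 to 5699 and 5865 to 8006 (siblings between times), 353 to 2134 and 55 to 495 (between lines), 0 and 0 to 1 (opposite directions), and 5 to 13, 6 to 12, 2 to 5 and 6 to 12 lists. Of 3574 values of named genes under the alternatives, 3234 kept their side of the threshold, 201 fell out, 139 came in and 0 changed sign across it. At this depth and number of libraries 2-fold changes were often missed in simulated counts.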

Other observations

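All values in this part were chosen only after the results were seen. Further counts of list members changed in siblings between the times stand against 6050 and 7840 changed genes of 19504, and no list was tested there. Of 16 retinoic acid pathway genes 10 rose and 2 fell in siblings of hs:dkk1b, and 12 rose and 2 fell in siblings of hs:wnt8a. Of 20 neural plate border, crest and placode genes 10 and 12 rose and 2 and 3 fell. Of 14 germ cell genes 9 and 8 fell, and 0 and 1 rose.

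A stage score was built from the 300 most rising and 300 most falling genes of the other line's siblings, with 0 and 1 as the sibling means at 5.5 and 7.5 hpf. In hs:dkk1b at 5.5 hpf, replicate 2 had scores of -0.406 in siblings and -0.432 in transgenic embryos, against 0.173 to 0.288 in the other 4 libraries. In the replicate 1 pair of hs:dkk1b at 7.5 hpf, 15 of 23 chaperone genes were higher than in both other replicates, in siblings and in transgenic embryos alike. Across 21 Wnt feedback genes, which are not independent replicates, log2 fold changes of both transgenes had a Pearson r of -0.764 at 5.5 hpf and -0.609 at 7.5 hpf, against -0.0894 and -0.131 over all 19501 genes other than the transgenes.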
